A study of Mus musculus with 2 samples.

How the data were processed

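Expression was measured in 2 libraries of sorted immune cells from orthotopic pancreatic tumours, 1 from exercised and 1 from sedentary mice. Per the labels, female mice of 9 weeks received 100000 FC1242 cells, tumours were digested at day 21, 3 mice per group were pooled, and 100000 CD45-positive cells that excluded propidium iodide were sorted for a 3-prime library with version 2 chemistry. Per the submitters' processing notes, reads were handled with bcl2fastq and Cell Ranger against mm10, whose versions are not given. The deposited values are raw UMI counts per gene and cell barcode, already filtered by the authors to barcodes called as cells. The same 28692 gene identifiers were listed for both libraries, and 28339 of them were found in GENCODE release M21, used only for gene positions on GRCm38.

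Cells with under 200 genes (2 in the exercise library and 4 in the no-exercise library) or over 10% mitochondrial UMIs (1 and 8) were left out. The barcodes with the highest Scrublet doublet scores were removed at 0.8% per 1000 barcodes, which took 144 and 58. Cells of both libraries were clustered together with Scanpy 1.11.5 and leidenalg 0.10.2 on genes seen in at least 3 cells. UMIs per cell were scaled to 10000 and log transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components, 15 neighbours and resolution 1 were used, with no integration of the libraries. Of 24 clusters, 23 were named by fixed marker lists, where 10 leading genes were ranked with 20 CPM added. Names ending in like mark classes known only from these transcripts. A T-like cluster counted as CD8 T-like where at least 80% of its cells held a Cd8a or Cd8b1 UMI and as CD4 T-like where at least 50% held a Cd4 UMI, and these 2 thresholds were set after the data were seen. Other software was Python 3.11.15, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and Matplotlib 3.10.9.

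Shares of cells carry exact Clopper-Pearson intervals, and ratios of shares carry intervals from the conditional binomial. For each class with at least 30 cells in each library, UMIs were summed per library and scaled to 1000000 UMIs of the class (CPM), with exact Poisson intervals on sums and exact conditional binomial intervals on ratios. All intervals are at the 95% level. The 25 gene lists, the named-gene rule, the filters and the first set of alternatives were fixed before the data were examined. A list member was measured with at least 20 UMIs over both libraries, and a list needed 3 measured members. Its median log2 ratio was set beside 10000 random lists of the same size matched on expression in 10 bins, and its interval came from 2000 Poisson redraws of the counts. Random lists carry no replication between mice, so a percentile describes these 2 libraries only.

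Genes named for the main classes were the 10 highest and 10 lowest among genes with at least 50 UMIs, ranked by the interval bound nearest to 1, leaving out mitochondrially encoded, ribosomal protein, haemoglobin and antigen receptor variable genes. Other classes gave 3 of each, each list gave up to 2 of each in a class, and a few genes of the IL-15 axis, of T cell effector function and of neutrophils were always reported. Only some of the genes that the rule gave are described, as for T-like, migratory dendritic-like and proliferating cells. Genes outside that rule are cluster leading genes, cell markers and the Y-linked genes, chosen after their values were seen. A gene was marked as one that free RNA can set where its level lay under 0.1 of that in another class. For shares of cells with a UMI, each cell was thinned to 500 UMIs, which left out 0 cells.

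With 1 library per group no test of a difference was possible, and no count of changed genes is given. The intervals were tested on simulated Poisson counts drawn from the pooled CD8 T-like rates, with known folds set in some of 8037 genes. They held the true ratio for 95.9% of unchanged genes and for 93.9% at a 2-fold difference. Of genes with a 2-fold difference 97.0% passed the 1.5-fold rule, and of unchanged genes 3.71% did. Share ratios held the true value in 96.5% of 2000 binomial draws. These draws follow the counting model that the intervals assume, so the coverage checks the calculation only. Spread between cells, with many UMIs of a gene in 1 cell, was not simulated. Alternatives covered the filters, doublet removal, clustering, scaling, weighting of cells, thinning and denominators, and 11 further alternatives were added after the data were seen.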

Results

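Immune cells were profiled by droplet single-cell RNA sequencing from pancreatic tumours of mice that ran on a treadmill and of mice that stayed sedentary. The tumours came from FC1242 cells, a mouse pancreatic cancer line with mutant Kras and p53, injected into the pancreas of wildtype mice. Exercised mice ran 5 days a week for 30 minutes a day at 15 cm per second, and tumours were taken at day 21. Each group was 1 library made from a pool of 3 mice and sorted for CD45, a surface protein of blood-derived cells, and for exclusion of a dye that enters dead cells. The series asked which immune populations differed in relative abundance between the tumours and whether gene expression differed within each population, and its title names the axis of IL-15 and its receptor alpha chain. The exercise library held 4244 barcodes and 16214507 UMIs (unique molecular identifiers, 1 per captured transcript), and the no-exercise library 2686 barcodes and 11429872 UMIs. After filtering, 4097 and 2616 cells remained, with medians of 3105 and 3050 UMIs per cell. With 1 library per group there are no replicates and no test, so every difference is between these pools. Parentheses after a value give its 95% interval, which covers counting error only and not the spread between mice.

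T-like cells made up the larger part of the exercise library and neutrophil-like cells were sparse in it. T-like cells took 63.9% (62.4 to 65.4) of the exercise library and 31.9% (30.1 to 33.7) of the no-exercise library, a ratio of 2.0 (1.85 to 2.17). Among them were CD8 T-like cells, the class that holds cytotoxic lymphocytes. They took 47.1% (45.5 to 48.6) of the exercise library and 17.9% (16.5 to 19.5) of the no-exercise library. Their ratio was 2.62 (2.37 to 2.91), for clusters that passed a threshold set after the data were seen and not for CD8 T cells in general. Cluster 5, with 217 and 225 cells, was left out, although 45.9% of its cells held a Cd8a or Cd8b1 UMI. Counting it in would lower the ratio, but that alternative was not run. Proliferating cluster 15, with 87 and 63 cells, was also outside the class, at 87.3%. CD4 T-like cells were 352 of 4097 cells against 34 of 2616, a ratio of 6.61 (4.64 to 9.70). All were of cluster 8, whose 10 leading genes included Cd4, Lag3, Maf, Areg, Ifng, Tox and Il10. In it 79.0% of cells held a Cd4 UMI and 35.0% a Cd8a or Cd8b1 UMI, so the ratio is for this cluster and not for CD4 T cells in general. The CD4 T-like ratio was 2.14 with cluster 11 counted in, where 43.9% of cells held a Cd4 UMI against the 50% asked of CD4 T-like clusters, a threshold set after the data were seen. Neutrophil-like cells, the class marked by S100a8, S100a9 and Cxcr2, took 3.56% (3.02 to 4.18) of the exercise library and 26.5% (24.8 to 28.3) of the no-exercise library, which was 7.44-fold lower in the exercise library.

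NK-like cells, innate cytotoxic lymphocytes, took 8.47% and 5.28% of the exercise and no-exercise libraries, a ratio of 1.61 (1.31 to 1.97). Shares were lower in the exercise library for B-like cells, at 5.08% and 8.72% with a ratio of 0.583 (0.480 to 0.706), and for monocyte-like cells, at 2.49% and 4.70% with a ratio of 0.530 (0.403 to 0.694). Among dendritic classes, cDC1-like cells, which present antigen to CD8 T cells, took 2.78% and 6.15% with a ratio of 0.452 (0.353 to 0.578). The ratio was 0.413 (0.258 to 0.653) for migratory dendritic-like cells, 0.403 (0.231 to 0.690) for plasmacytoid dendritic-like cells and 0.782 (0.613 to 0.998) for cDC2-like cells. Macrophage-like cells took 4.54% and 4.85%, with a ratio of 0.935 (0.742 to 1.18), and proliferating cells took 2.78% and 2.94%, with a ratio of 0.945 (0.702 to 1.28). Mast-like cells numbered 24 and 8, a ratio of 1.92 (0.833 to 4.93). The last 3 ratios have intervals that contain 1. The 10 leading genes of the mast-like cluster held 4 mast cell and 3 basophil markers, so basophils were not told apart in it.

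Shares sum to a whole, so a class that fills more of 1 library lowers every other share in it. As a share of cells other than T-like cells, an alternative chosen after the data were seen, neutrophil-like cells kept a ratio of 0.253 and NK-like cells had a ratio of 3.03. On that basis monocyte-like cells were at 0.999, macrophage-like cells at 1.76, proliferating cells at 1.78, and the ratios of B-like cells (1.10) and cDC2-like cells (1.47) turned to above 1. Shares of cells other than neutrophil-like cells, also chosen after the data were seen, gave lower ratios. These were 1.53 for T-like, 2.0 for CD8 T-like, 1.22 for NK-like, 0.712 for macrophage-like and 0.444 for B-like cells. With 15 principal components in place of 30 the CD8 T-like ratio was 4.0, and the CD4 T-like ratio could not be computed. With stress and cycle genes left out of the variable genes the proliferating ratio was 0.577. It also left its interval on the low side with at least 500 genes per cell (0.638), with up to 20% mitochondrial UMIs (0.610) and at resolution 0.5 (0.639). All shares are of sorted cells among deposited barcodes, whose lowest UMI totals were 1405 in the exercise library and 1557 in the no-exercise library.

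**Figure D1:**
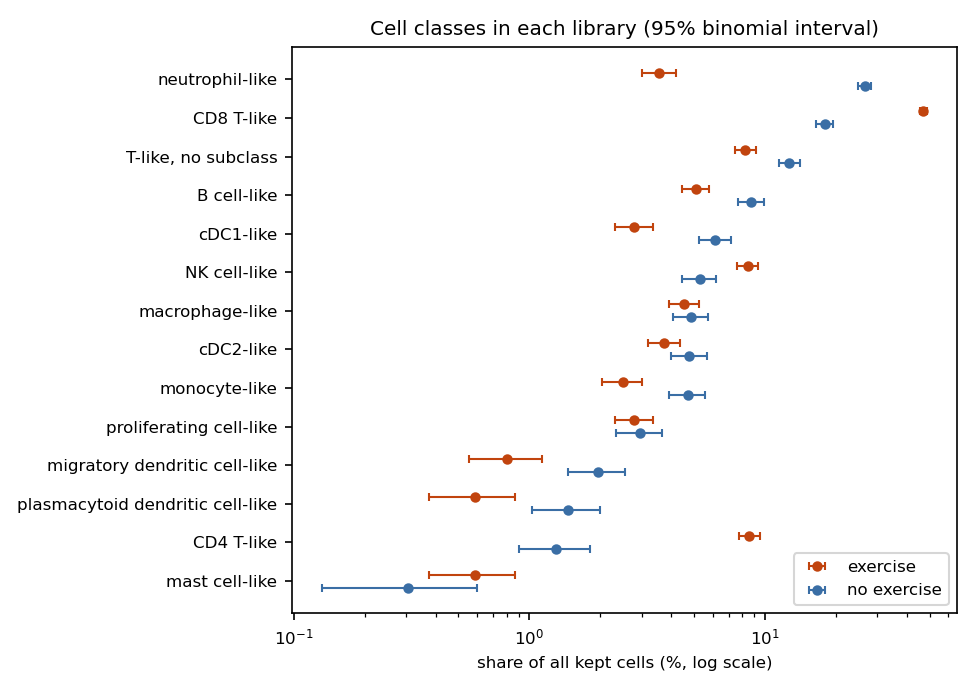
Share of all kept cells taken by each class (horizontal axis, percent, log scale) in the exercise library (orange) and the no-exercise library (blue), with exact 95% binomial intervals as bars. CD8 T-like cells stand at 47.1% and 17.9% and neutrophil-like cells at 3.56% and 26.5%.

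CD8 T-like cells of the libraries did not fall into the same clusters. Cluster 3, led by Gm156, Tcrg-C2 and the residency-associated chemokine receptor gene Cxcr6, held 7.0% of them in the exercise library and 75.9% in the no-exercise library. Cluster 0, led by Ccl5, Gzmb and Gzmk, held 39.2% of them in the exercise library and 3.2% in the no-exercise library, and cluster 1, led by Cd8b1, Gzmk and Ms4a4b, held 34.6% of them in the exercise library and 6.18% in the no-exercise library. Cluster 7, led by the chemokine genes Ccl1 and Xcl1, was the nearest to even, with 18.3% and 13.4%, and cluster 22, which also carried macrophage genes, held 17 and 6 cells. A cluster mostly from 1 library may be a property of that library, so every CD8 T-like value below sets mainly clusters 0, 1 and 7 of the exercise library against cluster 3 of the no-exercise library. The subclass names rest on thresholds set after the data were seen, which left clusters 5 and 11 without a subclass. These held 338 and 332 cells, or 12.9% and 39.8% of T-like cells, and cluster 5 was led by the naive-cell genes Lef1 and Tcf7. Naive and memory genes had a median log2 ratio of -0.81 (-0.87 to -0.66) over all T-like cells, and of 0.49 (0.23 to 0.88) within CD8 T-like cells, where cluster 3 alone gave -0.010.

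**Figure D2:**
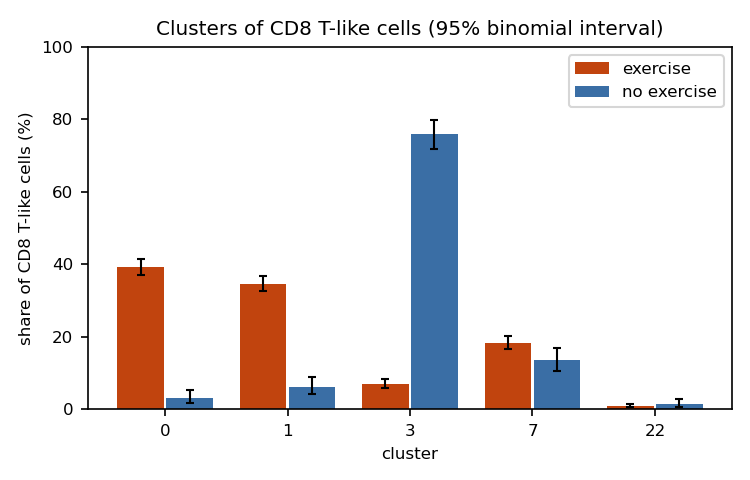
Share of each library's CD8 T-like cells in each cluster (vertical axis, percent) for the exercise library (orange, 1928 cells) and the no-exercise library (blue, 469 cells), with exact 95% binomial intervals. Cluster 3 holds 75.9% of the no-exercise cells and 7.0% of the exercise cells.

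Several effector genes were higher in CD8 T-like cells of the exercise library. Gzmb, which encodes the cytotoxic granule protease granzyme B, stood at 1288 (1262 to 1315) CPM in the exercise library and 411 (385 to 437) in the no-exercise library, a ratio of 3.14 (2.94 to 3.35), where CPM are UMIs per 1000000 UMIs of the class. Ifng, the gene of interferon gamma, was 2.15-fold (1.86 to 2.50) higher, Gzmk 1.85-fold (1.70 to 2.02) higher, and Ccl5, a T cell chemokine gene, 1.94-fold (1.92 to 1.96) higher. Cxcr3, which encodes the receptor for interferon-induced chemokines, was 2.80-fold (2.37 to 3.33) higher, at 182 and 64.8 CPM. In the other direction, Prf1, which encodes the pore-forming protein perforin, had a ratio of 0.704 (0.555 to 0.899), Ccl3 of 0.341 (0.327 to 0.355) and Ccl4 of 0.561 (0.547 to 0.575). Over the cytotoxic effector list, 5 of 16 measured members were at least 1.5-fold higher, 3 at least 1.5-fold lower and 8 in between. The median log2 ratio of that list was 0.27 (0.095 to 0.33), at percentile 99.8 among 10000 random lists matched on expression.

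The share of CD8 T-like cells with a UMI had the same directions once every cell was thinned to 500 UMIs, since unthinned depths differed (medians 3319.5 and 4548 UMIs). A Gzmb UMI was held by 30.7% (28.6 to 32.8) and 17.1% (13.8 to 20.8) of cells in the exercise and no-exercise libraries, a Gzmk UMI by 20.9% and 13.4%, an Ifng UMI by 7.78% and 3.84% and a Cxcr3 UMI by 9.91% and 3.84%. Before thinning these shares were 67.4% and 45.8%, 69.7% and 55.4%, 32.7% and 23.2% and 44.0% and 23.0%. In B-like cells, which should lack these genes and show free RNA (median depths 2090 and 2077 UMIs), the thinned shares were 0.481% and 1.32% for Gzmb and 0.481% and 0.439% for Cxcr3. Cxcr3 depended on the clusters compared, with a ratio of 0.885 among cells of cluster 7 alone and 2.33 among cells of cluster 3 alone. Many other genes did too. Within cluster 3 alone, 28 of 45 single-gene ratios in CD8 T-like cells left their counting interval and 2 turned direction. Within cluster 7 alone, 29 of 48 left it and 4 turned. The ratios above thus also hold the difference in cluster shares.

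Inhibitory receptor genes went both ways in CD8 T-like cells. Pdcd1, the gene of PD-1, was close to even at 623 and 667 CPM, a ratio of 0.933 (0.881 to 0.989), and a Pdcd1 UMI was held by 24.5% and 29.6% of cells thinned to 500 UMIs. Ctla4, which encodes another inhibitory receptor, was 4.51-fold (3.75 to 5.46) higher in the exercise library. The inhibitory receptor and exhaustion list had a median of -0.11 (-0.22 to -0.066), with 2 of 12 members at least 1.5-fold higher and 2 at least 1.5-fold lower, and the median was 0.11 in cluster 7 alone. Homing and residency receptor genes were mostly higher, with 8 of 12 at least 1.5-fold higher and a median of 0.64 (0.55 to 0.81) at percentile 100. Cxcr6 (0.948, 0.911 to 0.986) and Cd44 (0.638, 0.529 to 0.771) were exceptions, and Cxcr6 was above 1 within cluster 3 (1.07) and within cluster 7 (1.76). Ccr2 had a ratio of 3.99 (2.81 to 5.83) but lay under 0.1 of its monocyte level, so free RNA can set it.

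Type I interferon response genes were higher together in CD8 T-like cells of the exercise library, with 10 of 15 members at least 1.5-fold higher, 0 at least 1.5-fold lower and a median of 0.82 (0.57 to 1.00) at percentile 100. Isg15, an antiviral ubiquitin-like protein gene, was 2.90-fold (2.26 to 3.77) higher and Stat1, a transcription factor gene of interferon signalling, 2.48-fold (2.08 to 2.97) higher. The median of the type I list was 0.50 within cluster 3 alone and 0.34 within cluster 7 alone. Interferon gamma response and antigen presentation genes had a median of 0.31 (0.15 to 0.39), with 5 of 17 higher and 5 lower by the 1.5-fold rule, and 7 of them at levels free RNA can set, and a median of 0.12 within cluster 3 alone. Among the members above that level, Gbp2 was 1.93-fold (1.48 to 2.56) higher and H2-D1 1.48-fold (1.44 to 1.53) higher. Immediate early genes, which also answer to tissue dissociation, had a median of 0.45 (0.28 to 0.83), led by Nr4a1 (4.20, 3.25 to 5.52) and Klf6 (3.05, 2.73 to 3.41), with 5 members at levels free RNA can set, and it was 1.12 without them. Within cluster 3 alone this median was -0.10 and within cluster 7 alone -0.17. Proliferation genes were lower, with a median of -0.41 (-0.69 to -0.22) and 6 of 13 at least 1.5-fold lower, among them Stmn1 (0.257, 0.212 to 0.310) and the replication gene Mcm5 (0.371, 0.292 to 0.472), although cycling cells also formed a separate class.

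By the rank fixed for single genes, the highest in CD8 T-like cells of the exercise library included Ly6c2 (9.29, 6.66 to 13.3) and Ly6a (5.92, 4.84 to 7.32), surface proteins of memory and activated lymphocytes. Areg, the gene of the growth factor amphiregulin, had a ratio of 6.74 (4.15 to 11.7), with 52.9% of the few UMIs of the no-exercise library in 1 cell. Gpr183, an oxysterol-guided migration receptor gene, had a ratio of 5.52 (4.07 to 7.66) and Rgs2, a regulator of G protein signalling, of 4.28 (3.79 to 4.84). The others were Gramd3 (6.82, 4.73 to 10.2), 5430421N21Rik (7.77, 4.01 to 17.2), Chrne (81 and 2 UMIs, ratio 13.4, 3.60 to 113) and Tcrg-C3 (124 and 1 UMIs, ratio 41.1, 7.24 to 1635). Within cluster 7 alone the 5430421N21Rik ratio was 0.922. The lowest included Serpina3f, a protease inhibitor gene (0.111, 0.0746 to 0.163), the transporter gene Slc16a11 (0.139, 0.104 to 0.184), Tnfsf8, the gene of CD30 ligand (0.118, 0.0724 to 0.187), Penk, the enkephalin precursor gene (0.140, 0.0975 to 0.199), Nrgn (0.179, 0.155 to 0.208) and the replication gene Gins2 (0.143, 0.0789 to 0.250). S100a8 (0.177, 0.147 to 0.212), S100a9 (0.196, 0.161 to 0.238), Cd81 (0.151, 0.0980 to 0.227) and Iglc1 (0.0258, 0.0101 to 0.0553) were also low, but each lay under 0.1 of its level in neutrophil-like, macrophage-like or B-like cells, so free RNA can set them.

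**Figure D3:**
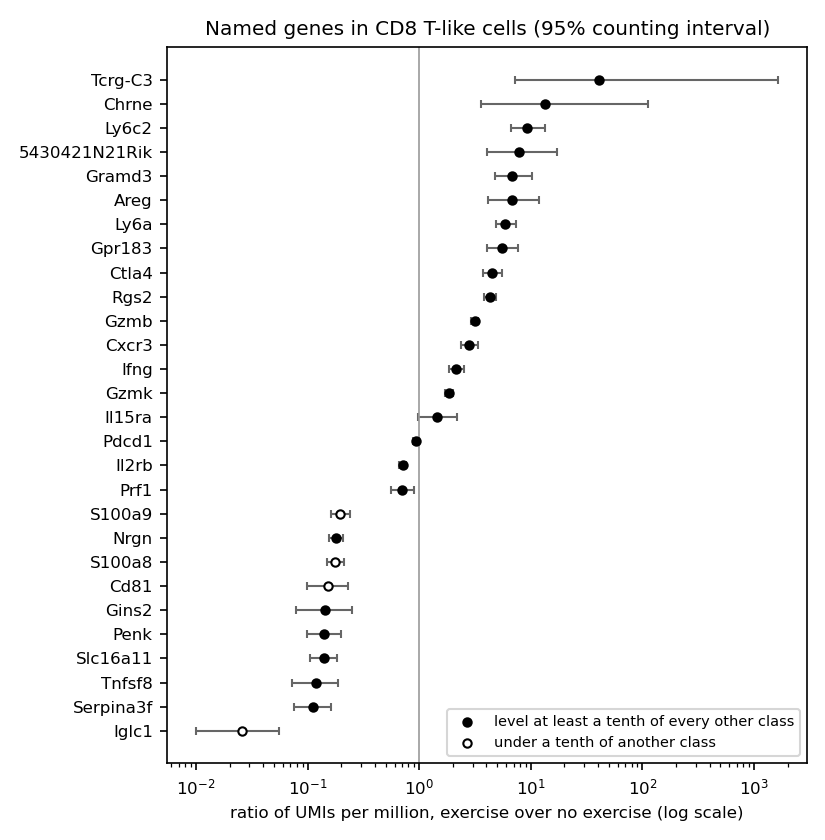
Ratio of CPM in CD8 T-like cells, exercise over no exercise (horizontal axis, log scale), for genes named by the fixed rule, with 95% counting intervals as bars. Gzmb lies at 3.14, Cxcr3 at 2.80 and Pdcd1 at 0.933, and open circles mark genes at levels free RNA can set.

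The IL-15 axis, named in the title, showed no common direction in CD8 T-like cells. Il15ra, the gene of the IL-15 receptor alpha chain, had 143 and 33 UMIs and a ratio of 1.44 (0.978 to 2.16), an interval that contains 1. Il2rb, which encodes the signalling chain shared by the IL-2 and IL-15 receptors, was lower in the exercise library at 303 and 428 CPM, a ratio of 0.709 (0.657 to 0.765), and stood at 1.04 within cluster 7 alone. Jak1, the kinase gene downstream, had a ratio of 1.21 (1.08 to 1.35), with 0.904 within cluster 3 alone, and Il2ra of 0.346 (0.187 to 0.641) on 24 and 23 UMIs. Il15 itself had 7 and 3 UMIs, which sets no direction. Over the list, 0 of 9 measured members were at least 1.5-fold higher and 1 lower, with a median of 0.12 (-0.024 to 0.26) at percentile 84.4 of random lists, and -0.079 within cluster 3 alone. After thinning to 500 UMIs, an Il15ra UMI was held by 1.35% (0.883 to 1.97) and 0.426% (0.0517 to 1.53) of CD8 T-like cells and an Il2rb UMI by 14.4% and 19.8%, beside 1.44% and 0.877% of B-like cells for Il2rb. For Il15ra 0 of 208 (0% to 1.76%) and 0 of 228 (0% to 1.6%) B-like cells of the exercise and no-exercise libraries held a UMI. In CD4 T-like cells, with only 34 cells in the no-exercise library, Il2rb was higher in the exercise library. It had 618 and 53 UMIs and a ratio of 1.35 (1.02 to 1.82). In NK-like cells the list median was 0.24 (-0.016 to 0.43) and in neutrophil-like cells 0.32 (-0.19 to 0.80), both with intervals that contain 0. In macrophage-like cells it was 0.77 (0.13 to 1.24) over 5 measured members, of which Stat3 had a ratio of 1.82 (1.04 to 3.31), while Il2rb lay at a level that RNA from NK-like cells can set.

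In the GRCm38 annotation these genes lie as follows, each span covering the whole annotated protein-coding gene. Gzmb (ENSMUSG00000015437) lies on chromosome 14, 56258838 to 56262260, Gzmk (ENSMUSG00000042385) on chromosome 13, 113171608 to 113225908, Ifng (ENSMUSG00000055170) on chromosome 10, 118441046 to 118445892 and Prf1 (ENSMUSG00000037202) on chromosome 10, 61297833 to 61304680. Cxcr3 (ENSMUSG00000050232) lies on chromosome X, 101731535 to 101734269, Pdcd1 (ENSMUSG00000026285) on chromosome 1, 94038305 to 94052553, Il2rb (ENSMUSG00000068227) on chromosome 15, 78479256 to 78495271, Il15ra (ENSMUSG00000023206) on chromosome 2, 11705290 to 11734317 and Il15 (ENSMUSG00000031712) on chromosome 8, 82331632 to 82403222. Cxcr2 (ENSMUSG00000026180) lies on chromosome 1, 74153989 to 74161246, Il1b (ENSMUSG00000027398) on chromosome 2, 129364570 to 129371139 and Arg1 (ENSMUSG00000019987) on chromosome 10, 24915221 to 24927484.

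NK-like cells carried higher levels of cytotoxic transcripts in the exercise library, and immediate early genes went both ways. Of 16 measured cytotoxic effector genes, 4 were at least 1.5-fold higher, 0 at least 1.5-fold lower and 12 in between, with a median of 0.40 (0.30 to 0.55) at percentile 100. Ccl4, a chemokine gene of activated lymphocytes, was 2.14-fold (1.91 to 2.42) higher and Gzmb 1.79-fold (1.57 to 2.04) higher, at 1145 and 641 CPM. Nr4a1, an orphan nuclear receptor gene induced by receptor signalling, was 3.34-fold (2.40 to 4.75) higher, Junb 1.89-fold (1.74 to 2.06) higher, Btg2 2.15-fold (1.85 to 2.52) higher and Tnfaip3, which encodes a brake on NF-kappa B signalling, 2.36-fold (1.69 to 3.35) higher. Hes1, a Notch target gene, had a ratio of 2.75 (2.10 to 3.67), Vps37b of 2.34 (1.98 to 2.78), Coq10b of 2.53 (1.71 to 3.87) and Rgcc of 4.65 (2.14 to 12) on 69 and 7 UMIs. Heat shock genes were lower, with a median of -0.26 (-0.41 to -0.13) at percentile 0.575, among them Hspa1a (0.162, 0.0764 to 0.319) and Hsp90ab1 (0.762, 0.677 to 0.858). Homing receptor genes had a median of 0.30 (0.12 to 0.50), the immediate early list 0.13 (0.011 to 0.46) with 5 of 13 members at least 1.5-fold higher and 1 lower, the inhibitory receptor list 0.28 (-0.084 to 0.72) and the type I interferon list -0.15 (-0.60 to 0.19). Mitochondrially encoded transcripts, with a median of -0.14 (-0.27 to -0.061), and ribosomal protein transcripts, with -0.28 (-0.31 to -0.25), were lower in the same cells. The lowest genes included S100a8, S100a9, Cxcl2, Il1b, Igkc and Ifitm1, all under 0.1 of their level in another class, and the higher Ccl9 lay under 0.1 of its monocyte level. Gm10073 (0.565, 0.495 to 0.645), Gm26917 (0.429, 0.307 to 0.6), Gm42418 (0.419, 0.278 to 0.630) and Nsfl1c (0.446, 0.273 to 0.728) were the lowest ranked genes above that level among those with at least 50 UMIs.

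Neutrophil-like cells of the libraries differed little in their granulocyte programme. The granulocytic suppressor and inflammatory list had a median of 0.084 (-0.086 to 0.14), with 15 of 20 members within 1.5-fold. Il1b, the gene of the cytokine IL-1 beta, had a ratio of 1.07 (1.03 to 1.10) and Cxcl2, a neutrophil-attracting chemokine gene, of 1.13 (1.10 to 1.17). Cxcr2, the chemokine receptor gene that guides neutrophils out of the marrow, was lower at 547 and 716 CPM, a ratio of 0.764 (0.653 to 0.890), and a Cxcr2 UMI was held by 16.4% (10.8 to 23.5) and 29.8% (26.4 to 33.4) of cells thinned to 500 UMIs. In B-like cells it was 0 of 208 (0% to 1.76%) cells and 2 of 228. Before thinning that share was 54.8% and 71.9%, at median depths of 1968 and 2075 UMIs. Antigen presentation genes were higher, with 9 of 15 members of the interferon gamma list at least 1.5-fold higher and a median of 0.72 (0.46 to 0.79) at percentile 100. In that list H2-K1, a class I histocompatibility gene, was 2.22-fold (1.96 to 2.51) higher and B2m 1.74-fold (1.63 to 1.86) higher, while class II genes Cd74 (0.684, 0.564 to 0.822) and H2-Ab1 (0.683, 0.501 to 0.915) lay at levels free RNA can set, and Cd74 stood at 1.16 without doublet removal. H2-Q7, another class I gene, was 4.56-fold (3.2 to 6.5) higher. Il1a, the gene of IL-1 alpha, was 2.76-fold (2.18 to 3.48) higher, in a classically activated macrophage list with a median of 0.87 (0.27 to 1.18), which was 0.29 without cells holding a T cell marker UMI. Glycolysis and hypoxia genes had a median of 0.26 (0.18 to 0.33), led by the hypoxia-induced lipid droplet gene Hilpda (2.07, 1.88 to 2.28) and Pfkp (1.77, 1.28 to 2.41).

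Several of the extreme neutrophil-like values rest on few cells or on other cells' RNA. Elane (0 and 347 UMIs) and Mpo (0 and 58 UMIs), protease and peroxidase genes of neutrophil precursors, came from 1 cell of the no-exercise library, so no fold is given. Arg1, the arginase gene, had 18 and 37 UMIs, and its ratio of 2.43 (1.30 to 4.38) was 0.502 without the top cell of each library. Cxcl1 (0 and 65 UMIs) and the stefin gene Stfa3 (0 and 57 UMIs) came from 9 and 10 cells of the no-exercise library, with 47.7% and 47.4% of those UMIs in 1 cell, and the 0 of the exercise library allows up to 10.6 CPM of each. Stfa2 had 3 and 105 UMIs, a ratio of 0.143 (0.0289 to 0.428). Saa3, an acute-phase protein gene, had a ratio of 0.306 (0.189 to 0.470) with 72.7% of its exercise UMIs in 1 cell and 0.0981 without the top cells, Ifitm1 of 0.475 (0.439 to 0.514), Ifit1 of 0.168 (0.0341 to 0.508) and AY036118 of 0.198 (0.0632 to 0.475). T and NK transcripts were among the highest, as Ccl5 (9.62, 8.52 to 10.9), Cd3g (3.77, 2.67 to 5.31), Cd3d (3.62, 2.46 to 5.28), Trbc2 (3.81, 2.79 to 5.17), Nkg7 (3.34, 2.66 to 4.19), Ms4a4b (4.47, 3.00 to 6.63), AW112010 (4.0, 3.23 to 4.94) and Gzma (9.40, 6.62 to 13.5), each under 0.1 of its level in a T-like or NK-like class, and 1 cell held 69.8% of the exercise Gzma UMIs. Ccl4 had a ratio of 3.71 (3.42 to 4.02) in neutrophil-like cells.

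Macrophage-like cells of the exercise library carried less Fn1, S100a4 and Ccr2 and lower levels of several myeloid chemokine genes. Ccl9 was 8.71-fold (6.83 to 11.3) lower, Fn1, the fibronectin gene, 4.93-fold (3.65 to 6.75) lower, S100a4 5.04-fold (3.51 to 7.38) lower, S100a6 3.31-fold (2.75 to 4.02) lower and Ccr2, the monocyte chemokine receptor gene, 3.82-fold (2.47 to 6.07) lower. Alox5ap, which serves leukotriene synthesis, had a ratio of 0.320 (0.244 to 0.417), Itgam of 0.224 (0.117 to 0.402) and the lipase gene Lpl of 0.211 (0.0979 to 0.417). Myeloid chemokine genes had a median of -0.62 (-0.82 to -0.31) at percentile 0, with 6 of 11 at least 1.5-fold lower and 0 higher, among them Ccl6 (0.426, 0.389 to 0.465), whereas Ccl8 was 1.45-fold (1.20 to 1.75) higher. Arg1, which encodes arginase and marks alternative activation, was lower at 2116 and 2955 CPM, a ratio of 0.716 (0.663 to 0.773). The alternatively activated list went both ways, with 2 of 11 members at least 1.5-fold higher, among them Ccl24 (2.47, 2.16 to 2.84) and Mgl2 (1.56, 1.26 to 1.94), 5 lower, among them Folr2 (4 and 20 UMIs, ratio 0.161, 0.0400 to 0.480), and a median of -0.58 (-1.09 to -0.41). Chil3 (0.136, 0.0815 to 0.218) and Mmp9 (0.139, 0.0603 to 0.285) were low at levels free RNA can set, and 1 cell held 50% and 59.6% of their no-exercise UMIs.

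On the higher side, macrophage-like cells of the exercise library held more Mt2, a metal-binding metallothionein gene (3.84, 3.19 to 4.65), more Tgm2, the transglutaminase gene of tissue macrophages (3.33, 2.63 to 4.24), and more Il1a (3.86, 1.93 to 8.56). Interferon gamma response and antigen presentation genes had a median of 0.51 (0.45 to 0.59) at percentile 100, with 6 of 16 at least 1.5-fold higher, among them the GTPase gene Gbp2 (3.98, 2.41 to 6.91) and Cxcl9, a Cxcr3 ligand gene (2.70, 1.71 to 4.41). Cxcl10, another Cxcr3 ligand gene, had 13 and 25 UMIs there, and all of the no-exercise UMIs were in 1 cell. Glycolysis and hypoxia genes had a median of 0.39 (0.34 to 0.52), with Egln3 (3.22, 1.90 to 5.73) and Bnip3 (2.44, 1.82 to 3.32) highest, and fatty acid oxidation genes one of -0.34 (-0.52 to -0.024). The classically activated list had a median of 0.61 (0.49 to 1.48) and included Ccl5 (5.96, 5.13 to 6.96), at a level T-like cells can set. Mitochondrially encoded transcripts, a sign of RNA quality, were lower as well, with a median of -0.76 (-0.87 to -0.66) and 9 of 11 at least 1.5-fold lower.

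Macrophage-like values depended on which cells were kept. Without cells that held a T cell marker UMI, a setting chosen after the data were seen, the alternatively activated median was -0.0027, the classically activated median 0.34 and the Il1b ratio 0.811 against 1.52 (1.32 to 1.75) with them, and Il1b lay under 0.1 of its neutrophil level. Without doublet removal, S100a6 had a ratio of 1.12, and the proliferation median of 0.88 (0.53 to 1.23) turned to -0.075. Cxcr6, Cd8a, Trbc2, Nkg7, Klrd1, Ly6a and Ccl17 were among the highest genes of the class in the exercise library, and all but Klrd1 and Ly6a lay under 0.1 of their level in T-like or migratory dendritic-like cells.

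Saa3 and Lrg1 were lower in monocyte-like cells of the exercise library, and Tnfsf9 and Nr4a2 were higher in its cDC2-like cells. In monocyte-like cells Cxcl10 had 98 and 3 UMIs, a ratio of 47.1 (15.6 to 232), although 1 cell held 52.0% of the exercise UMIs. Saa3 was 27.6-fold (18.0 to 44.9) lower there, Lrg1, a secreted glycoprotein gene, 7.11-fold (5.37 to 9.58) lower and Wfdc21 6.78-fold (4.17 to 11.7) lower. Of their few exercise UMIs 1 cell held 66.7% for Saa3 and 88.9% for Wfdc21, so the other cells lay lower still. The type I interferon list had a median of 0.59 (0.41 to 0.81) and the alternatively activated list one of -0.82 (-1.43 to -0.28) in monocyte-like cells. Their classically activated median of 0.78 (0.67 to 0.89) turned to -0.36 without cells holding a T cell marker UMI. In cDC2-like cells, which present antigen to CD4 T cells, Tnfsf9, the gene of the costimulatory 4-1BB ligand, was 11.6-fold (6.88 to 21.2) higher, Nr4a2 9.84-fold (5.56 to 19.0) higher and Ccl4 7.16-fold (6.07 to 8.48) higher. Immediate early genes had a median of 1.12 (1.02 to 1.23) there, the classically activated list 1.37 (1.23 to 2.48) and the interferon gamma list 0.38 (0.28 to 0.48). In cDC1-like cells the genes ranked highest (Ccl5, Gzmb, Trbc2) and lowest (S100a8, S100a9, Cxcl2) all lay at levels that free RNA can set, and 1 cell held 74.5% of the exercise Gzmb UMIs and 45.2% of the Ccl5 UMIs.

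**Figure D4:**
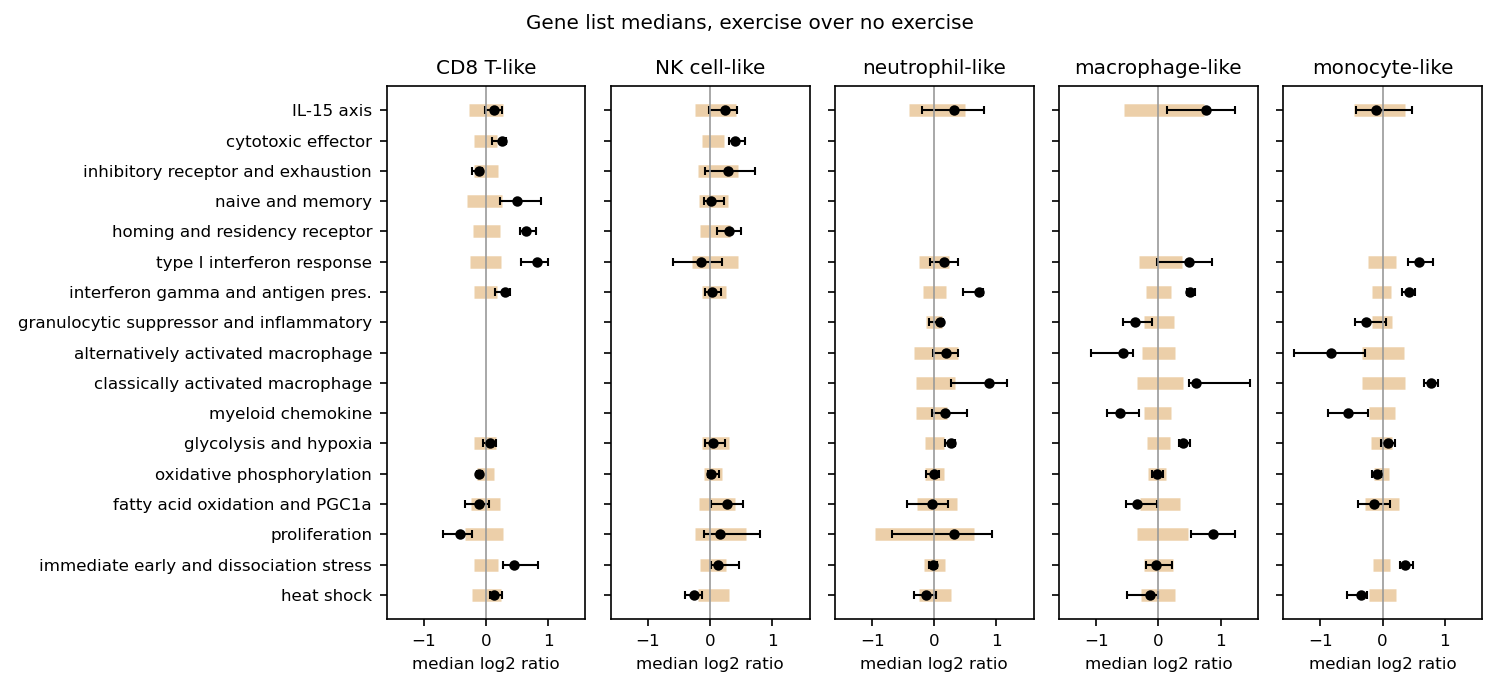
Median log2 ratio of each gene list, exercise over no exercise (horizontal axis), in CD8 T-like, NK-like, neutrophil-like, macrophage-like and monocyte-like cells, with 95% counting intervals from redrawn counts as bars and the central 95% of matched random lists as tan bands. In CD8 T-like cells the type I interferon list lies at 0.82 and the IL-15 axis at 0.12.

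B-like cells of the exercise library held fewer heat shock transcripts and more interferon-response transcripts. Of 9 measured heat shock genes, 7 were at least 1.5-fold lower and 0 higher, with a median of -0.74 (-0.91 to -0.52) at percentile 0, among them the chaperone genes Hspe1 (0.566, 0.450 to 0.709) and Hsp90aa1 (0.601, 0.493 to 0.729). The type I interferon median was 0.65 (0.43 to 1.06), with Stat1 2.81-fold (1.88 to 4.28) higher and Ifi27l2a 1.67-fold (1.30 to 2.16) higher, and the interferon gamma and antigen presentation median was 0.49 (0.41 to 0.58), with H2-K1 1.48-fold (1.32 to 1.65) higher. Nr4a1, which antigen receptor signalling can induce, was 3.36-fold (2.43 to 4.71) higher, Plk2 3.21-fold (2.09 to 5.07) higher, Rrad 4.02-fold (2.22 to 7.70) higher and Ly6a 2.37-fold (1.96 to 2.89) higher. The rise of Nr4a1 was not particular to B-like cells. It was also higher in CD8 T-like, NK-like, cDC1-like (3.37, 2.11 to 5.52) and proliferating cells (8.59, 4.34 to 19.4). Whether receptor signalling or tissue dissociation set it was not tested. Some of the largest values rested on single cells. Of the 13164 Iglc1 UMIs of the no-exercise library 12466 were in 1 cell, and without the top cells the Iglc1 ratio of 0.0440 (0.0401 to 0.0482) was 0.738. Of the Mt1 and Mt2 UMIs of the exercise library 98.3% and 96.3% were in 1 cell each, and of Pycard 66.5%, while 1 cell held 91.7% of Ly6c2 UMIs of the no-exercise library. Ighm had a ratio of 0.361 (0.351 to 0.370), with 58.4% of exercise and 31.6% of no-exercise UMIs in 1 cell, and of 0.221 without the top cells. The plasma cell markers Igha and Mzb1 were among the 10 leading genes of the cluster. Antibody-secreting cells were not told apart in this class and can set its immunoglobulin values. Cxcl2, Ccl3, Il1b, S100a8 and S100a9 were lower and Ccl5 and Trbc2 higher at levels that neutrophil-like and T-like cells can set. AY036118, low in neutrophil-like cells as well, had 7 and 43 UMIs and a ratio of 0.196 (0.0745 to 0.440). Slpi had a ratio of 0.253 (0.169 to 0.371), which turned to 2.74 with cells thinned to 500 UMIs.

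CD4 T-like cells could be compared only with 34 cells of the no-exercise library. Gzma, a granzyme gene, had 2391 and 6 UMIs, a ratio of 46.2 (21.2 to 126), Ccl5 a ratio of 3.90 (3.70 to 4.11) and Areg 279 and 1 UMIs, a ratio of 32.3 (5.75 to 1281). The cytotoxic effector median was 0.44 (0.13 to 0.61), with 5 of 14 members at least 1.5-fold higher and 1 lower, and the heat shock median -0.67 (-0.80 to -0.53). Penk was 11.2-fold (7.83 to 16.1) lower and Tff1 15.4-fold (8.36 to 29.0) lower, with 71.9% of exercise Penk UMIs and 87.5% of no-exercise Tff1 UMIs in 1 cell each, and all Hspb1 UMIs of the no-exercise library (52) were in 1 cell. Over all T-like cells Il10, the gene of an immunosuppressive cytokine, was 7.76-fold (3.84 to 18.3) higher, Areg 7.03-fold (5.07 to 10.0) higher and Igfbp4, a gene of the naive-like cluster 5, 5.15-fold (4.18 to 6.36) lower, which includes the difference in subclass shares.

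Metabolic and quality lists lay closer to even in CD8 T-like cells. Their medians were 0.071 (-0.051 to 0.16) for glycolysis and hypoxia, -0.12 (-0.14 to -0.067) for oxidative phosphorylation, -0.12 (-0.33 to 0.049) for fatty acid oxidation, 0.13 (0.059 to 0.26) for heat shock (though -0.13 within cluster 3 alone), -0.19 (-0.24 to -0.16) for mitochondrially encoded and -0.24 (-0.25 to -0.22) for ribosomal protein transcripts. The adrenergic receptor list holds genes of receptors for adrenaline and noradrenaline and of the receptor kinase Grk2. It had 3 measured members and a median of 0.39 (0.053 to 0.78). Fibroblast genes had 4 and 2 UMIs in these cells, acinar genes 111 and 63, and erythroid genes 78 and 38. Tumour-like epithelial cells, named by Krt8 and Krt18, numbered 5 and 6 in the sorted libraries. The labels call the mice female, whereas a UMI of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d or Uty was held by 44.8% and 37.3% of immune cells and an Xist UMI by 0 of 4092 (at most 0.0901%) and 3 of 2610 cells.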

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

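The signals below, outside the main measurement, were picked out because they lie above what a count of 0 allows. The tests of male mice and of mixed sexes were chosen only after the Y-linked result was seen. A UMI of Ddx3y, Eif2s3y, Kdm5d or Uty, genes found only on the Y chromosome, was held by 44.8% of 4092 immune cells of the exercise library and 37.3% of 2610 of the no-exercise library, in mice labelled female. Eif2s3y stood at 91.9 and 65.2 CPM and Ddx3y at 61.1 and 51.3. Xist, which is transcribed from the inactive X chromosome of female cells, had 0 and 3 UMIs in these cells.

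After thinning to 1000 UMIs the lower share of cells with a Y-linked UMI was 12.3%, which restates the observation and is no independent test of male mice. If some mice of a pool were female, at least 1% of cells should hold an Xist UMI, and the higher share was 0.115% (0.0237 to 0.336), so female cells can have made up only a small part. If Y-linked RNA came from male tumour cells, it should stay near the tumour-like ratio of Y-linked to Krt8 and Krt18 UMIs, but tumour-like cells had 0 Y-linked and 189 keratin UMIs, and the ratio in immune cells was 2885 times theirs (at least 2346), taking their 0 as 3 counts. With these 2 sources excluded, the immune cells of both libraries were in the main male, against the label, and the files do not tell how the label came about. No biological explanation was tested, and since both libraries carry the signal, its presence does not set them apart. Its size did differ, with a Y-linked UMI in 16.1% (15.0 to 17.3) of immune cells of the exercise library thinned to 1000 UMIs and 12.3% (11.1 to 13.6) of the no-exercise library. The cause of that difference was not tested.

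Tumour-like epithelial cells, expressing Krt8 and Krt18, numbered 5 in the exercise library and 6 in the no-exercise library despite the sort for CD45. In 1 of the 6 cells 34 Xist UMIs were found.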

How the results depend on the processing

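The CD8 and CD4 thresholds and the alternatives on cluster 11, denominators, single clusters, T marker cells, top cells and free-RNA members were chosen after the data were seen. Under the alternatives fixed before, the ratio of shares stayed at 1.94 to 2.06 for T-like, 2.43 to 4.0 for CD8 T-like, 0.133 to 0.139 for neutrophil-like, 1.55 to 1.65 for NK-like, 0.568 to 0.587 for B-like and 0.879 to 1.07 for macrophage-like cells. Turned values were counted only where the interval of the reported value left out equality. Of 176 alternative values of class shares 2 turned direction in that sense, while macrophage-like and proliferating ratios, whose intervals contain 1, lay on both sides of it. Direction also turned, of 629 list medians, for 4 of lists the report leads with and 6 of others and, of 1725 single-gene ratios, for 15. Another 334 single-gene ratios, 52 other list medians and 2 shares of cells with a UMI left their counting interval without being counted as turned. No value could be computed where a library kept too few UMIs or measured members, for T-like classes of cells other than T-like cells, for Il15ra in CD4 T-like cells at 1000 UMIs, and for CD4 T-like cells with each library clustered on its own, since no such cluster formed in the no-exercise library. The CD4 T-like share ratio also had no value with 15 components. No paired analysis was possible because each group was 1 pooled library. Depth limits genes with few UMIs, as the wide intervals of Il15, Il15ra and Il2ra in CD8 T-like cells show.

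The following values turned direction or left the counting interval, and the cause was not tested. With 15 components the share ratio was 4.0 for CD8 T-like cells. With at least 500 genes per cell the share ratio was 0.638 for proliferating cells. With up to 20% mitochondrial UMIs the share ratio was 0.610 for proliferating cells. At resolution 0.5 the share ratio was 0.639 for proliferating cells. With stress, cycle and ribosomal genes left out of the variable genes the share ratio was 0.577 for proliferating cells. With each library clustered on its own share ratios were 0.760 for monocyte-like and 0.549 for cDC2-like cells. With cells thinned to 500 UMIs the ratio in B-like cells was 2.74 for Slpi. With cells weighted equally the median log2 ratio in NK-like cells was 0.28 for cytotoxic, and the median log2 ratio in macrophage-like cells was 0.34 for interferon gamma. With median of ratios scaling the median log2 ratio in B-like cells was 0.37 for interferon gamma and -0.087 for mitochondrially encoded. With no doublet removal the ratio in macrophage-like cells was 1.12 for S100a6, 1.70 for S100a9 and 0.981 for Rrm2, and the ratio in neutrophil-like cells was 1.16 for Cd74, and the median log2 ratio in macrophage-like cells was 0.26 for glycolysis and -0.075 for proliferation. Without thinning the ratio of shares with a UMI in cDC2-like cells was 0.935 for Il1b.

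Alternatives chosen after the data were seen gave these values, and the cause was not tested. With cluster 11 counted as CD4 T-like the share ratio was 2.14 for CD4 T-like cells. Of cells other than T-like cells share ratios were 3.03 for NK-like, 1.10 for B-like, 0.253 for neutrophil-like, 0.999 for monocyte-like, 1.76 for macrophage-like, 0.853 for cDC1-like, 1.47 for cDC2-like, 0.779 for migratory dendritic-like, 0.761 for plasmacytoid dendritic-like and 1.78 for proliferating cells. Of cells other than neutrophil-like cells share ratios were 1.53 for T-like, 2.0 for CD8 T-like, 1.22 for NK-like, 0.444 for B-like, 0.712 for macrophage-like, 0.344 for cDC1-like and 0.595 for cDC2-like cells. Within cluster 3 the ratio in CD8 T-like cells was 0.904 for Jak1 and 1.07 for Cxcr6, and the median log2 ratio in CD8 T-like cells was -0.079 for IL-15 axis, -0.010 for naive and memory, 0.52 for homing, 0.50 for type I interferon, 0.12 for interferon gamma, -0.10 for immediate early and -0.13 for heat shock. Within cluster 7 the ratio in CD8 T-like cells was 0.922 for 5430421N21Rik, 1.04 for Il2rb, 0.885 for Cxcr3 and 1.76 for Cxcr6, and the median log2 ratio in CD8 T-like cells was 0.11 for exhaustion, 0.037 for naive and memory, 0.34 for type I interferon, -0.78 for proliferation and -0.17 for immediate early. Without cells of other classes that held a T cell marker UMI the ratio in B-like cells was 0.730 for Pycard, and the ratio in macrophage-like cells was 0.811 for Il1b, and the median log2 ratio in B-like cells was 0.35 for interferon gamma and -0.051 for mitochondrially encoded, and the median log2 ratio in macrophage-like cells was -0.82 for granulocytic, -0.0027 for alternatively activated, 0.34 for classically activated, 0.28 for glycolysis, -0.53 for fatty acid oxidation, 0.16 for proliferation and 0.033 for ribosomal protein, and the median log2 ratio in monocyte-like cells was -0.36 for classically activated, and the median log2 ratio in neutrophil-like cells was 0.36 for glycolysis. Without list members that free RNA can set the median log2 ratio in macrophage-like cells was -0.84 for myeloid chemokine, and the median log2 ratio in neutrophil-like cells was 0.80 for interferon gamma, and the median log2 ratio in CD8 T-like cells was 0.48 for interferon gamma and 1.12 for immediate early. Without the top cell of each library the ratio in migratory dendritic-like cells was 0.770 for Tm4sf5, against 4.45 (2.90 to 6.96) with those cells. In neutrophil-like cells the ratio without the top cells was 0.502 for Arg1.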

Other observations

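Further transcripts stood out after the data were seen. Gcg, the proglucagon gene of islet alpha cells, was found in CD4 T-like cells, with a UMI in 22 of 352 cells of the exercise library (471 UMIs, at most 95 in a cell) and 3 of 34 of the no-exercise library (37 UMIs). No UMI of the insulin genes Ins1 and Ins2 was seen in those cells of either library, and no Gcg UMI in B-like, NK-like or macrophage-like cells. In CD8 T-like cells 6 of 1928 cells of the exercise library held 10 Gcg UMIs, beside 4 Ins1 and Ins2 UMIs and 2 of other islet genes in the class, against 0 of 469 cells (0% to 0.783%) of the no-exercise library, and 1 of 125 cDC2-like cells of the no-exercise library held 1 Gcg UMI. An unnamed cluster, led by the interferon-induced genes Ifit1, Ifit3, Isg15, Rtp4 and Cxcl10, held 23 cells of the exercise library and 5 of the no-exercise library, a ratio of 2.94 (1.09 to 9.89). In that cluster 85.7% of cells held a Cd8a or Cd8b1 UMI. Its cells were left out of the CD8 T-like class and of the type I interferon values given for it.

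T cell transcripts in other classes were higher in the exercise library, and free RNA was not told apart from remaining doublets. Ccl5 stood at 687 and 169 CPM in B-like cells and 1765 and 136 in monocyte-like cells of the exercise and no-exercise libraries, where 1 monocyte-like cell held 35.6% of the exercise UMIs, and a T cell marker UMI was held by 47.1% and 32.0% of B-like cells. T cell receptor variable genes were unevenly used, though 3-prime libraries catch few of their reads. Trav12-2 took 58.4% of 101 Trav UMIs in cluster 1 of the exercise library, and Trav15-2-dv6-2 43.9% of 244 in cluster 0.

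For the low share of neutrophil-like cells in the exercise library, the tests of broken cells and of cells other than T-like cells were chosen only after the result was seen. If neutrophils of that suspension had broken open after the sort, their RNA should remain in the fluid, yet S100a8 and S100a9 in B-like cells stood at 39.8 and 403 CPM, a ratio of 0.0986 (0.0608 to 0.152). RNA of cells that broke open before the sort need not remain, so their loss at that stage is not addressed. If a UMI threshold had removed them, the ratio among deep cells should reach 0.5, but with at least 3000 UMIs the ratio was 0.0959 (0.0566 to 0.154) and with at least 5000 it was 0.198 (0.0667 to 0.489) on 6 and 27 neutrophil-like cells. That prediction assumes neutrophils of equal depth in both libraries, and the medians of the kept ones were 1967.5 and 2075 UMIs. Shallower cells would be fewer above any threshold, so loss of shallow neutrophils is not excluded. If added T-like cells alone had diluted them, their ratio among other cells should be near 1, and it was 0.253 (0.210 to 0.303). A lower number of neutrophils in the exercised tumours remains possible. So do loss of shallow cells and a difference between pools in the mice, the digestion or the sort, which 1 library per group cannot separate.

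For CD8 T-like cells that fell into different clusters, the comparison with other classes was chosen only after the result was seen. A technical difference acting on all cells should separate other classes as much, but 84.8% of neighbours of CD8 T-like cells came from their own library against 59.6% for NK-like, 58.4% for B-like, 51.5% for cDC1-like and 57.8% for macrophage-like cells, 26.7 percentage points above their median, and 68.5% for monocyte-like and 60.6% for cDC2-like cells, which were not in that median. Classes were not matched in cell number, with 469 CD8 T-like cells per library against 138 NK-like, 208 B-like, 114 cDC1-like and 127 macrophage-like cells. The share can depend on that number, so the gap alone cannot exclude a technical difference. After thinning to 1000 UMIs the gap to NK-like cells was 22.5 points. Of neighbours of CD8 T-like cells 79.5% still came from their own library, against 49.9% in even mixing, so a difference in depth alone cannot account for their separation. If 1 expanded clone filled a library's main cluster, 1 Trbv gene should lead there, and Trbv29 took 72.0% (50.6 to 87.9) of 25 Trbv UMIs in cluster 3 of the no-exercise library, but also 65.0% of 20 in cluster 7 of the exercise library, whose largest clusters 0 and 1 stayed below that, with Trbv12-2 at 35.8% (23.1 to 50.2) and 35.9%. Since cluster 3 had 2 leading Trav genes, Trav7d-2 (21 of 43 UMIs) and Trav3-3 (11), a few expanded clones per mouse pool and an effect of exercise on CD8 T cells both remain possible.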
